A study of Mus musculus with 72 samples.

How the data were processed

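Livers of C57BL/6J (B6) and DBA/2J (DBA) mice of both sexes were profiled by RNA sequencing after 12 weeks on a Western diet with a control, a low or a high content of isoleucine and a fast of 16 h. The labels place 72 libraries in 12 groups of 6, with 2 strains, 2 sexes and 3 diets. The groups were taken from the labels' strain, sex and diet fields, and columns of the count table were matched to libraries by title; 0 columns were left unmatched. The design text places the start of the diets at 6 weeks of age, whereas the treatment text of the labels gives the age at start as 18 weeks, which is also the age in the age field. The labels name a polyA-enriched stranded preparation in one field and a stranded total RNA guide in another. They give no time of day of sampling and no batch, and do not say whether each library came from a separate animal; p-values therefore measure the spread between libraries, part of which may be technical.

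The authors aligned reads to GRCm38.p5 and made expected counts per Ensembl gene, per the labels' protocols; the aligner and the counting program are not given in the sources used here. These deposited expected counts are estimates that need not be whole, and 9.56% of the nonzero values were not whole. The submitters' processing notes name R 3.4.3, edgeR and limma. The authors also deposited a table of their own comparisons with log2 fold changes, p-values and test scores (t and F statistics, not used here) for 14729 genes, 120 of which have no line in the count table. A deposited table of linear fold changes was not used here. The count table lists 50308 genes; its last line is incomplete, with values for 3 libraries, and 50307 genes were used. Gene symbols and positions came from an Ensembl annotation of GRCm38, which matched 50255 of the identifiers; the other 52 held 0.017% of all counts. The annotation holds 1830 genes after the last identifier of the table, which were not analysed here. The highest total of a library was 51.1 in units of 1e6 counts and the median 24.1, and 22676 genes had no count in any library.

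Expected counts were rounded to whole numbers, genes with low counts were removed with edgeR's filterByExpr by group, and library sizes were scaled by TMM (factors of 0.84 to 1.14). The remaining 14954 genes were tested with edgeR's quasi-likelihood test with robust dispersions in a single fit of all 72 libraries with a mean per group; the common biological coefficient of variation was 0.21. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and log2 fold changes are given with standard errors (SE). Low and high isoleucine were each compared with control within each of the 4 strain-sex classes and as the mean of the 4 class effects. High isoleucine was further compared with low isoleucine, differences of the diet effects between strains and between sexes were tested as interaction terms, and males were compared with females and DBA with B6 on the control diet. Levels are counts per 1e6 counts of the TMM-scaled library size (CPM). The number of libraries on the side of a fold change was counted against the mean of the control group. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and, for data.table, 1.17.8.

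The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, per comparison of a diet with control, genes from the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and a regular symbol, up to 4 members of each list with the lowest adjusted p, and a panel of 12 genes (Fgf21, Gdf15, Asns, Trib3, Scd1, Fasn, Srebf1, Cyp7a1, Pck1, Cidec, Bckdhb and Igf1) whatever their test, with Xist and Ddx3y as checks of the labels. For sex and strain the genes named come from the 5 largest rises and the 5 largest falls. A gene so named in a comparison is also given in others. The 34 lists were amino acid response (ATF4 targets), branched-chain amino acid breakdown, amino acid catabolism and urea cycle, fatty acid synthesis, cholesterol synthesis, bile acid and sterol handling, fatty acid oxidation (PPARA targets), gluconeogenesis and fasting, lipid droplets, unfolded protein response, oxidative phosphorylation, NRF2 and glutathione, CAR and PXR targets, acute phase response, interferon response, MHC class II, cell cycle, circadian clock, male-biased and female-biased liver genes, and markers of Kupffer cells, infiltrating macrophages, stellate cells, sinusoidal endothelium, cholangiocytes, lymphocytes, neutrophils, hepatocytes, pericentral and periportal hepatocytes, pancreas, adipose tissue, erythroid cells and mitochondrially encoded genes. Lists were tested with limma's camera on voom values with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. Counts of members are over all genes tested, and a count adjusted over the list alone follows where it differs. The camera test was repeated with the correlation estimated from the data, and that p is given as the adjusted p with an estimated correlation. Sex-biased lists come from textbook knowledge and hold several multigene families.

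Library titles carry a number that 2 libraries of a group share, with 3 numbers per group; the labels do not say what it means. Libraries that shared a number resembled each other more: the chi-square per gene between their counts had a median of 34.97 (36 pairs, 13.43 to 120.19) against 74.34 for other pairs of a group (144 pairs, 17.8 to 226.65). These values are far above sampling noise, so the files of a pair are not copies of each other, but they do not show whether the libraries of a number came from separate animals. Each library was counted as a replicate. The correlation within a number estimated over all genes was 0.24, so the number was also fitted as a random block with limma voom, and the result is called the value with the title-number block. Within a strain and sex each number lies within a single diet group, so a difference between numbers can add to a difference between diets, and the block widens the errors.

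The test was tried on counts simulated for all 72 libraries. They were drawn from the library sizes, the mean of each gene in each strain-sex class and the dispersions of the main fit. The changes were placed in the B6 male low isoleucine group, which was compared with its controls. Among 14837 simulated genes it recovered 27 of 66 genes changed 1.5-fold (40.9%), 53 of 67 changed 2-fold (79.1%) and 62 of 66 changed 4-fold (93.9%), with median estimates of 0.56, 1.03 and 1.97, and 7 of its 149 calls were unchanged genes. Limma voom called 139 changed genes and 7 unchanged genes. The number of genes changed in the simulation before the filter on low counts was 200. A simulated list of 30 moved genes had a camera p of 1.69e-21 and an unmoved list of 30 a p of 0.889. With a correlation of 0.25 simulated within title numbers and no effect, edgeR called 0 to 6 of 14861 genes per comparison and the block fit called 0. The title-number variation was drawn separately for each gene. The simulation therefore cannot show how many false calls arise when many genes shift together in a title number.

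The alternatives were scaling by RLE, DESeq2's Wald test, limma voom without and with quality weights, the title-number block, sums of the 2 libraries of a number (3 per group), no filter on low counts, and a fit of only the 18 libraries of a class; list tests were repeated with RLE scaling and with fry. Fits without B6 female control library 4 or without DBA male high isoleucine library 3, and camera on summed libraries, were chosen after seeing the data. Genes with near-identical copies (the Mup, Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Gstm, Sult2a, Ugt2b and C1r families, and histones) are uncertain, since shared reads could be divided between copies. Reads of both strains were counted on the C57BL/6J reference, so sequence differences of DBA can lower or raise its counts.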

Results

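Liver RNA was sequenced from fasted B6 and DBA mice of both sexes kept for 12 weeks on a Western diet, a diet used to induce obesity and fatty liver, with a control, a low or a high content of isoleucine. Isoleucine is an essential branched-chain amino acid. The design compares livers at different isoleucine contents of a Western diet. It holds no group on another diet, so the response to the Western diet itself is not measured. The 72 libraries fall into 12 groups of 6. Enough counts to be tested were held by 14954 genes. Xist, the noncoding RNA of the inactive X chromosome, lay between 216 and 1040 CPM in the female libraries and at 0.985 CPM or less in the male libraries. Ddx3y, a Y-linked helicase gene, lay between 15.7 and 50.4 CPM in the male libraries and at 0 in the female libraries, except for 0.568 CPM in B6 female control library 4. On principal components of the log2 CPM values, strain accounted for 95.9% of the variance of the first component, sex for 89.7% of that of the second and diet for 64.1% of that of the third.

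**Figure D1:**
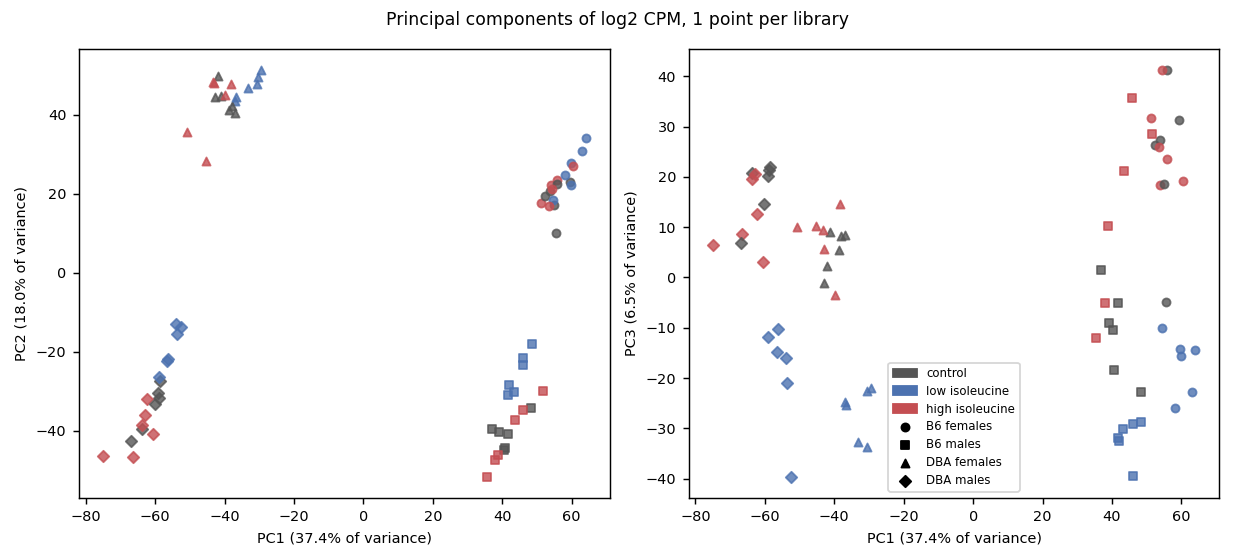
Principal components of log2 CPM of the 72 libraries (points), with the percentage of variance on each axis; colours mark diets and symbols mark strain and sex. The first component holds 37.4% of the variance, the second 18% and the third, on which low isoleucine libraries lie below the control libraries of their class, 6.5%.

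Low isoleucine was compared with control as the mean effect of the 4 strain-sex classes (24 libraries per diet). Sult1e1, the estrogen sulfotransferase, rose with a log2 fold change of 2.49 ± 0.31 (SE, adjusted p = 3.3e-09), Eif4ebp3, a repressor of cap-dependent translation, by 2.18 ± 0.27, and Cdkn1a, a cyclin-dependent kinase inhibitor, by 2.09 ± 0.30. By class Sult1e1 was at 1.84 in B6 females, 4.42 in B6 males, 1.59 in DBA females and 2.12 in DBA males. The B6 male value raises the average and starts from control levels near 0. Lepr, the leptin receptor (1.89 ± 0.25), and Igfbp1, a secreted binding protein of insulin-like growth factors (1.66 ± 0.31), also rose. Dbp, a transcription factor driven by the circadian clock, fell most, with a log2 fold change of -2.88 ± 0.24 (adjusted p = 2.9e-14), and lay below the control mean in 6 of 6 low isoleucine libraries of each class. Gbp10, a guanylate-binding protein (-2.61 ± 0.28), Rbm24, an RNA-binding protein (-2.57 ± 0.42), and Themis, a gene of T cell development (-2.11 ± 0.42), fell too. Dbp lies on chromosome 7 from 45705088 to 45710203 (GRCm38). In all, 5647 genes passed the test, 2662 higher and 2985 lower, of which 81 were at least 2-fold higher and 182 at least 2-fold lower.

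Interferon response genes were lower with low isoleucine. Of 26 measured, 25 fell and 0 rose (26 fell when adjusted over the list alone), with a median log2 fold change of -0.94 (camera adjusted p = 3.2e-26, and adjusted p = 0.039 with an estimated correlation). Ifit1, which binds viral RNA, fell by 1.76 ± 0.14 on the log2 scale (adjusted p = 4.8e-15), Ifit3 by 1.43 ± 0.13, Oas1a, an activator of RNase L, by 1.34 ± 0.13, and Ifih1, a sensor of double-stranded RNA, by 0.74 ± 0.07. Ifit1 and Ifit3 lie on chromosome 19, from 34640871 to 34650009 and from 34583531 to 34588731. All 7 MHC class II genes fell (median -0.59, adjusted p = 0.015, and 0.75 as the adjusted p with an estimated correlation), Cd74, the invariant chain, by 0.67 ± 0.16. Of 13 Kupffer cell markers 10 fell and 1 rose (median -0.45, adjusted p = 0.015, and adjusted p = 0.8 with an estimated correlation). Of 15 lipid-associated and infiltrating macrophage markers 10 fell and 0 rose (11 adjusted over the list alone, median -0.50, adjusted p = 0.015, and adjusted p = 0.75 with an estimated correlation). Among the Kupffer cell markers that fell was Cd68, a lysosomal protein of macrophages (-0.62 ± 0.14). Among the lipid-associated and infiltrating markers were Cx3cr1, the fractalkine receptor (-0.61 ± 0.16), and Ccl2, a monocyte attractant (-1.59 ± 0.27). Of 19 lymphocyte markers 3 fell (1 adjusted over the list alone), among them Cd4 (-0.91 ± 0.18), and of 4 neutrophil markers 0 passed the test (medians -0.13 and -0.09, adjusted p = 0.41 and 0.98). Sinusoidal endothelial markers went the other way: 9 of 14 rose and 0 fell (10 rose adjusted over the list alone; median 0.28, adjusted p = 0.0016, and adjusted p = 0.75 with an estimated correlation), with Bmp2, an endothelial signal for hepcidin, up by 0.57 ± 0.08 and Kdr, the VEGF receptor, up by 0.52 ± 0.09. Stellate cell and collagen genes had 4 of 22 members lower (3 adjusted over the list alone; median -0.08, adjusted p = 0.51), among them Col3a1 (-0.65 ± 0.13).

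Genes of the circadian clock moved in opposite directions. The activators Npas2 (1.75 ± 0.19), Arntl (1.56 ± 0.18) and Clock (0.49 ± 0.08) and the repressor Cry1 (1.02 ± 0.10) rose, while Dbp and Nr1d1, the repressor REV-ERB alpha (-1.32 ± 0.16), fell. In total 5 of 19 clock genes rose and 13 fell (6 and 13 adjusted over the list alone; median -0.53), and the list did not pass camera (adjusted p = 0.05, or 0.042 without B6 female control library 4). Arntl lies on chromosome 7 from 113207465 to 113314126 and Cry1 on chromosome 10 from 85131700 to 85185064. The cell cycle list had 10 of 24 members lower and 1 higher (13 and 1 adjusted over the list alone; median -0.43, adjusted p = 0.037, and adjusted p = 0.75 with an estimated correlation). E2f1, a transcription factor of S phase entry, fell by 1.37 ± 0.16 and Ccne1, cyclin E, by 0.97 ± 0.20. The member that rose was Cdkn1a, which blocks the cycle. Without B6 female control library 4 the cell cycle list had an adjusted p of 0.055.

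Some genes of fasting metabolism rose with low isoleucine. Of 18 genes of gluconeogenesis and fasting 10 rose and 2 fell (11 and 3 adjusted over the list alone; median 0.21, adjusted p = 0.015, and adjusted p = 0.75 with an estimated correlation). Gadd45b, a stress-response gene, rose by 1.45 ± 0.20, and Ppargc1a, a coactivator of gluconeogenesis and mitochondrial genes, by 0.72 ± 0.15. Of 35 PPARA targets of fatty acid oxidation 9 rose and 3 fell (median 0.05, adjusted p = 0.015, and adjusted p = 0.75 with an estimated correlation). Pdk4, which restrains pyruvate oxidation (1.59 ± 0.22), Cyp4a14, a fatty acid omega-hydroxylase of a family with similar copies (0.91 ± 0.09), and Angptl4, an inhibitor of lipoprotein lipase (0.62 ± 0.09), rose. Bdh1, a ketone body dehydrogenase, fell by 0.50 ± 0.07. Of 32 oxidative phosphorylation genes 13 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.0026, and adjusted p = 0.75 with an estimated correlation). Among them were Cycs, cytochrome c (0.34 ± 0.06), and Cyc1 (0.22 ± 0.04). Of 13 mitochondrially encoded genes 4 rose (2 adjusted over the list alone; median 0.17, adjusted p = 0.14).

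In amino acid metabolism, 13 of 32 genes of amino acid catabolism and the urea cycle rose and 4 fell (median 0.12), and the list did not pass camera (adjusted p = 0.067, or 0.046 without B6 female control library 4). Mat1a, which makes S-adenosylmethionine (0.54 ± 0.08), Ahcy (0.42 ± 0.07) and Cps1, which starts the urea cycle (0.54 ± 0.11), rose. Otc, the next enzyme of that cycle, fell by 0.45 ± 0.06. Of 31 ATF4 targets of the amino acid response 8 rose and 3 fell (median 0.07, adjusted p = 0.27). Asns, asparagine synthetase, was at 1.29 ± 0.38, Gars, glycyl-tRNA synthetase, at 0.23 ± 0.05, Atf4 itself at 0.25 ± 0.07 and Shmt2, a mitochondrial serine hydroxymethyltransferase, at -0.28 ± 0.06. Branched-chain amino acid breakdown had 2 of 25 members higher and 5 lower (median -0.04, adjusted p = 0.27), and the unfolded protein response 7 of 23 higher and 0 lower (5 adjusted over the list alone; median 0.13, adjusted p = 0.096).

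Lipid and sterol genes moved both ways. Cholesterol synthesis had 10 of 25 members lower and 1 higher (median -0.28, adjusted p = 0.015, and adjusted p = 0.83 with an estimated correlation), with Stard4, a sterol carrier, down by a log2 change of -0.67 ± 0.13. Fatty acid synthesis had 11 of 24 lower and 4 higher (12 and 4 adjusted over the list alone; median -0.22, adjusted p = 0.14). Pklr, liver pyruvate kinase, fell by 0.66 ± 0.11 and Lpin1, a phosphatidate phosphatase, rose by 1.17 ± 0.23. Of 24 lipid droplet genes 7 rose and 10 fell, with Plin5, a coat protein of lipid droplets, at 0.81 ± 0.09, and Pparg and Fitm1, genes of fat storage, at -0.67 ± 0.10 and -1.32 ± 0.20. That list's median was 0.02, its mean -0.13 and its test direction up (adjusted p = 0.98). Bile acid and sterol handling had 4 of 23 higher and 4 lower (median -0.02, adjusted p = 0.95). Cyp27a1, a sterol hydroxylase, was at 0.42 ± 0.06. NRF2 and glutathione genes had 7 of 20 lower and 0 higher (median -0.14, adjusted p = 0.067). CAR and PXR targets had 3 of 16 higher and 5 lower (median 0.04, mean -0.07, direction up, adjusted p = 0.96), and the acute phase list 6 of 24 each way (median 0, mean -0.08, direction up, adjusted p = 0.98), with Cxcl1, a neutrophil attractant, down at -1.43 ± 0.17.

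Male-biased liver genes, many of them driven by pulsatile growth hormone, had 16 of 22 members lower and 1 higher (median -0.57, adjusted p = 0.00086, and adjusted p = 0.75 with an estimated correlation). Ghr, the growth hormone receptor, fell by 0.45 ± 0.06 and C6, a complement component, by 0.63 ± 0.13. Female-biased genes had 8 of 26 higher and 5 lower (median 0.35, adjusted p = 0.29). Cyp39a1, an oxysterol hydroxylase, was at 1.69 ± 0.17. Hepatocyte markers had 4 of 12 higher and 1 lower (median 0.10, adjusted p = 0.29). Pericentral genes had 2 of 12 each way (3 higher and 2 lower adjusted over the list alone; median -0.07, mean -0.01, direction up, adjusted p = 0.82). Axin2, a target of Wnt signalling, was at 0.49 ± 0.09. Periportal genes had 4 of 12 higher and 2 lower (median 0.17, adjusted p = 0.59). Cyp2f2 was at -0.74 ± 0.08. Cholangiocyte markers had 2 of 9 higher and 1 lower (1 each way adjusted over the list alone; median -0.09, mean -0.08, direction up, adjusted p = 0.96), erythroid markers 2 of 6 lower (median -0.06, adjusted p = 0.46), and adipose markers 1 of 3 lower, namely Cfd (median -0.10, adjusted p = 0.96; Cfd -2.34 ± 0.62, adjusted p = 0.093 with the title-number block). The single measured pancreas marker fell (-0.40, list adjusted p = 0.2).

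**Figure D2:**
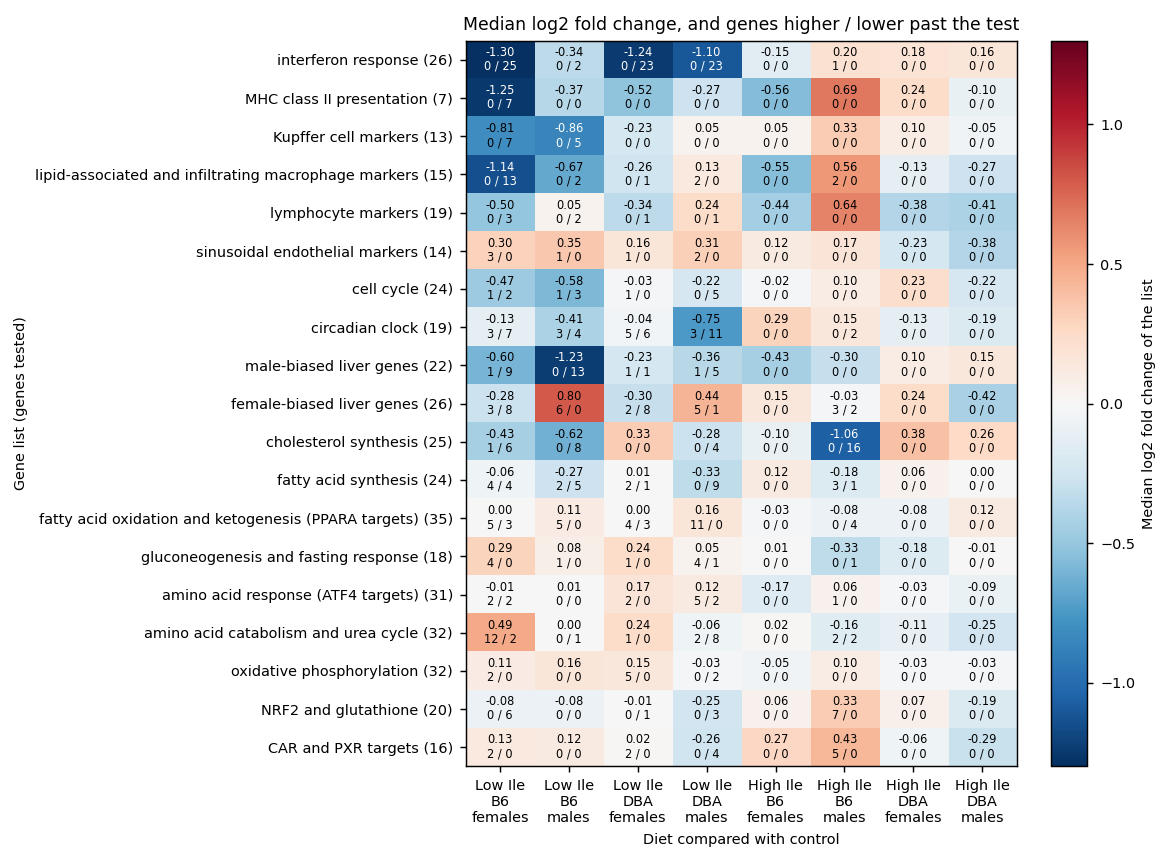
Median log2 fold change (colour scale and upper number) of 19 gene lists for low and high isoleucine against control in each strain-sex class, with 6 libraries per group. The lower numbers are the genes higher and lower past the test, and brackets hold the number of genes tested.

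In B6 females, low isoleucine changed 3115 genes, 1425 higher and 1690 lower (6 libraries per group); 1852 passed with the title-number block. Eif4ebp3 rose by 3.01 ± 0.56 on the log2 scale (adjusted p = 8.7e-05, higher in 6 of 6 libraries), Mt2, a metallothionein, by 2.40 ± 0.51 (6 of 6), and Nr4a1, an immediate early nuclear receptor, by 2.17 ± 0.45 (5 of 6). Amino acid catabolism had 12 of 32 members higher and 2 lower (16 and 3 adjusted over the list alone; median 0.49, adjusted p = 7.5e-06, and adjusted p = 0.59 with an estimated correlation). Risers were Tat, tyrosine aminotransferase (1.45 ± 0.29), Bhmt, which remethylates homocysteine (1.42 ± 0.28), and Cps1 (1.05 ± 0.23). The gluconeogenesis list had 4 of 18 higher and 0 lower (median 0.29, adjusted p = 0.0018, and adjusted p = 0.16 with an estimated correlation). Ppargc1a was at 1.71 ± 0.31 and Foxo1 at 0.70 ± 0.15. Of 26 interferon genes 25 fell (median -1.30, adjusted p = 1.2e-17, and adjusted p = 0.16 with an estimated correlation). Cxcl10, a T cell attractant, fell by 2.43 ± 0.34 (adjusted p = 1e-06, lower in 6 of 6 libraries). Alongside, 13 of 15 infiltrating macrophage markers fell (14 adjusted over the list alone; median -1.14, adjusted p = 6.4e-07, and adjusted p = 0.16 with an estimated correlation). Mmp12, macrophage elastase, was at -3.20 ± 0.65, Cx3cr1 at -1.61 ± 0.31 and Ccr2 at -1.13 ± 0.26. All 7 MHC class II genes fell (median -1.25, adjusted p = 1.8e-05, and adjusted p = 0.42 with an estimated correlation). Ciita, their transactivator, was at -1.46 ± 0.34. Of 13 Kupffer cell markers 7 fell (10 adjusted over the list alone; median -0.81, adjusted p = 0.0039, and adjusted p = 0.87 with an estimated correlation). A1bg, a secreted protein of female liver, fell by 4.13 ± 0.61, Osgin1, an oxidative stress gene, by 1.95 ± 0.32 and Bdh1 by 1.05 ± 0.14. Male-biased genes (1 higher and 9 lower, median -0.60, adjusted p = 0.04, or 0.12 without B6 female control library 4) and endothelial markers (3 of 14 higher, median 0.30, adjusted p = 0.0078, or 0.052 without that library) each had an adjusted p of 0.87 with an estimated correlation.

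In B6 males, 749 genes passed, 261 higher and 488 lower, and 238 with the title-number block; with quality weights for libraries the share of higher genes moved from 34.8% to 45.2%. Cyp2b9, a female-biased cytochrome P450 with similar copies, rose by 4.69 ± 0.96 (adjusted p = 0.0014, 6 of 6 libraries), and Mup21, a major urinary protein of males from a large family, fell by 2.45 ± 0.32 (adjusted p = 5.2e-07, 6 of 6). Of 22 male-biased genes 13 fell (19 adjusted over the list alone; median -1.23, adjusted p = 1.5e-20, and adjusted p = 0.022 with an estimated correlation), with C6 at -1.40 ± 0.25. Of 26 female-biased genes 6 rose (9 rose and 1 fell adjusted over the list alone; median 0.80, adjusted p = 0.00025, and adjusted p = 0.44 with an estimated correlation). Slco1a4, an organic anion transporter, was at 1.41 ± 0.29 and Fmo2 at 0.95 ± 0.21. Sult1e1 rose by 4.42 ± 0.85, with an adjusted p of 0.12 with the block. Its control libraries here lay at 0.654 CPM or less, so the size of this fold is uncertain. Cholesterol synthesis had 8 of 25 members lower (17 adjusted over the list alone; median -0.62, adjusted p = 2.9e-11, and adjusted p = 0.44 with an estimated correlation). Stard4 was at -1.23 ± 0.26. Tff3, a secreted trefoil peptide, fell by 4.08 ± 0.84, and Saa1, an acute phase protein, by 3.45 ± 0.81 (adjusted p = 0.085 with the block). Interferon genes had 2 of 26 lower (7 adjusted over the list alone; median -0.34, adjusted p = 0.00069, and adjusted p = 0.68 with an estimated correlation). Kupffer cell markers had 5 of 13 lower (11 adjusted over the list alone; median -0.86, adjusted p = 1.4e-08, and adjusted p = 0.44 with an estimated correlation), and infiltrating macrophage markers 2 of 15 lower (4 adjusted over the list alone; median -0.67, adjusted p = 0.00049, and adjusted p = 0.44 with an estimated correlation). The cell cycle (3 of 24 lower, 1 higher, median -0.58) and the stellate cell lists (3 of 22 lower, median -0.20) had an adjusted p of 0.0015 and 0.021, and 0.44 and 0.68 as the adjusted p with an estimated correlation. PPARA targets (5 of 35 higher, 9 adjusted over the list alone, median 0.11), oxidative phosphorylation (0 of 32, median 0.16) and endothelial markers (1 of 14, 4 adjusted over the list alone, median 0.35) had an adjusted p of 0.00036, 0.0002 and 0.00046, and 0.53, 0.6 and 0.58 as the adjusted p with an estimated correlation.

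In DBA females, 1763 genes passed, 765 higher and 998 lower, and 827 with the title-number block. Gucy2e, a membrane guanylate cyclase, rose by 3.29 ± 0.57 (adjusted p = 0.00011, 6 of 6 libraries), Cdkn1a by 2.54 ± 0.59, Lpl, lipoprotein lipase, by 2.36 ± 0.39, Pdk4 by 2.05 ± 0.44 and Cry1 by 1.77 ± 0.21 (6 of 6 libraries each). Interferon genes had 23 of 26 members lower (25 adjusted over the list alone; median -1.24, adjusted p = 0.02 with an estimated correlation). Oas1a was at -2.06 ± 0.27 (adjusted p = 2.9e-07), Usp18, which removes ISG15, at -1.59 ± 0.21 and Ifih1 at -1.05 ± 0.14, each lower in 6 of 6 libraries. Here 0 of 13 Kupffer cell markers and 1 of 15 infiltrating macrophage markers fell. Oxidative phosphorylation genes rose in 5 of 32 cases (6 adjusted over the list alone; median 0.15, adjusted p = 4.8e-05, and adjusted p = 0.93 with an estimated correlation). Mitochondrially encoded genes rose in 2 of 13 (4 adjusted over the list alone; median 0.54, adjusted p = 0.0035, and adjusted p = 0.93 with an estimated correlation). The amino acid catabolism list (1 of 32 higher, median 0.24) and the unfolded protein response (3 of 23 higher, 5 adjusted over the list alone, median 0.23) each had an adjusted p of 0.04, and 0.93 as the adjusted p with an estimated correlation. Female-biased genes had 2 of 26 higher and 8 lower (median -0.30, adjusted p = 0.031, and adjusted p = 0.93 with an estimated correlation), with A1bg at -3.93 ± 0.60 and Cyp3a16, of a family with similar copies, at -5.62 ± 0.84. The single pancreas marker fell (list adjusted p = 0.031, and adjusted p = 0.1 with an estimated correlation). Vnn1, a pantetheinase and PPARA target, fell by 0.91 ± 0.21.

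In DBA males, 2645 genes passed, 1119 higher and 1526 lower, and 1650 with the title-number block. Igfbp1 rose by 3.80 ± 0.70 (adjusted p = 5.1e-05, 6 of 6 libraries), Lepr by 3.31 ± 0.57 and Gadd45b by 3.15 ± 0.47 on the log2 scale. PPARA targets had 11 of 35 members higher (12 adjusted over the list alone; median 0.16, adjusted p = 4e-06, and adjusted p = 0.45 with an estimated correlation). Cyp4a14 was at 2.05 ± 0.18 (adjusted p = 3.2e-13, 6 of 6) and Ehhadh, a peroxisomal enzyme, at 1.47 ± 0.22. Fatty acid synthesis had 9 of 24 lower (10 adjusted over the list alone; median -0.33, adjusted p = 0.0038, and adjusted p = 0.5 with an estimated correlation). Thrsp, a lipogenic regulator, fell by 3.36 ± 0.55, Scd1, stearoyl-CoA desaturase, by 2.02 ± 0.51 and Pklr by 1.17 ± 0.23. Pparg fell by 1.53 ± 0.20, Mogat1, a monoacylglycerol acyltransferase, by 2.91 ± 0.54, and Fitm1 by 2.64 ± 0.37. Clock genes had 11 of 19 lower and 3 higher (12 and 4 adjusted over the list alone; median -0.75, adjusted p = 0.0012, and adjusted p = 0.24 with an estimated correlation). Ciart was at -3.86 ± 0.67, Usp2 at -3.35 ± 0.57 and Arntl at 2.26 ± 0.38. Interferon genes had 23 of 26 lower (25 adjusted over the list alone; median -1.10, adjusted p = 0.057 with an estimated correlation). Ifit1 was at -2.20 ± 0.27 and Ifi44 at -1.95 ± 0.27 (6 of 6 libraries each). At the same time 0 of 13 Kupffer cell markers fell and 2 of 15 infiltrating macrophage markers rose, including Cd9, a tetraspanin (1.20 ± 0.20). Mas1, an angiotensin peptide receptor (-5.37 ± 0.74), Themis (-4.07 ± 0.66), Nptx1, a neuronal pentraxin (-3.18 ± 0.47), and Cd4 (-2.03 ± 0.33) fell. Cholesterol synthesis (4 of 25 lower, 5 adjusted over the list alone, median -0.28) and CAR and PXR targets (4 of 16 lower, median -0.26), such as Cyp2c55 (-2.94 ± 0.51) and Cyp2a5 (-2.48 ± 0.52), both of families with similar copies, had an adjusted p of 0.044 and 0.039, and 0.75 as the adjusted p with an estimated correlation. The unfolded protein response (2 of 23 higher, 1 adjusted over the list alone, median 0.22, adjusted p = 0.023) and endothelial markers (2 of 14 higher, median 0.31, adjusted p = 0.018) likewise had an adjusted p of 0.75 with an estimated correlation. Amino acid catabolism had 8 of 32 lower and 2 higher (8 and 3 adjusted over the list alone), Otc at -0.81 ± 0.12 and Gpt2, an alanine aminotransferase, at -0.86 ± 0.18.

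**Figure D3:**
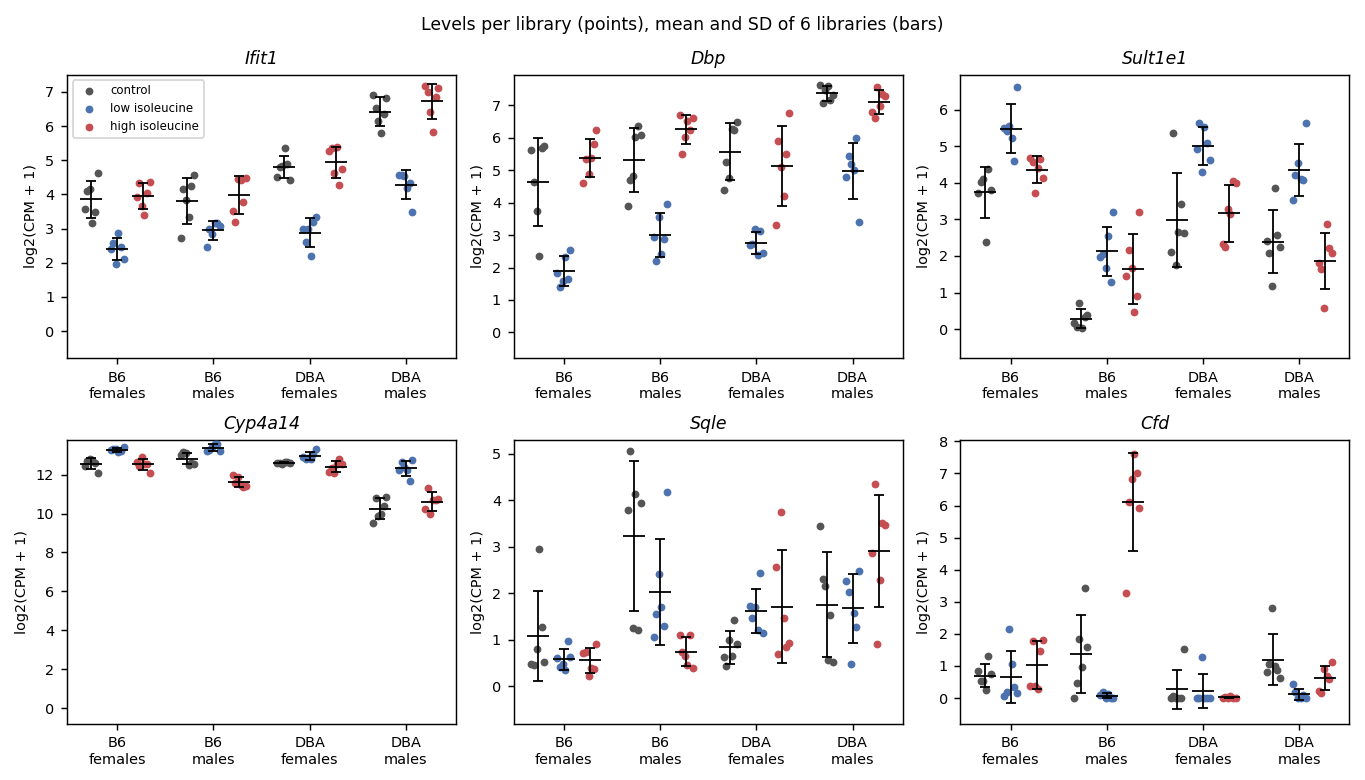
Level of Ifit1, Dbp, Sult1e1, Cyp4a14, Sqle and Cfd as log2(CPM + 1) by strain-sex class and diet (colours). Points are libraries, and bars are the mean and SD of 6 libraries.

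The effect of low isoleucine differed between the sexes (male minus female) for 999 genes, 453 higher and 546 lower; 300 passed with the title-number block, and without a filter on low counts the share of higher genes was 57.1% in place of 45.3%. Thrsp responded more negatively in males by 3.10 ± 0.52 (difference -3.10, adjusted p = 0.00016), Ciart by a difference of -3.22 ± 0.62 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by -1.66 ± 0.41. Vldlr, the VLDL receptor, responded more positively (2.20 ± 0.42), as did Bdh1 (0.77 ± 0.14) and Cyp4a14 (0.76 ± 0.17). Of 32 amino acid catabolism genes 10 responded more negatively in males (15 adjusted over the list alone; median -0.43, adjusted p = 6.4e-07, and adjusted p = 0.45 with an estimated correlation). Of 35 PPARA targets 9 responded more positively (10 adjusted over the list alone; median 0.20, adjusted p = 1.9e-06, and adjusted p = 0.45 with an estimated correlation). On average over the strains interferon genes fell less in males, by a median of 0.47 (2 of 26 past the test, 9 adjusted over the list alone, adjusted p = 1.9e-05, and adjusted p = 0.67 with an estimated correlation). The list's median was -1.30 in B6 females and -0.34 in B6 males, and -1.24 in DBA females and -1.10 in DBA males; a difference of the sex difference between strains was not tested. Cholesterol synthesis responded more negatively in males (3 of 25, median -0.48, adjusted p = 1.9e-05, and adjusted p = 0.67 with an estimated correlation). Female-biased genes responded more positively (4 of 26, 5 adjusted over the list alone, median 0.93, adjusted p = 0.00083, and adjusted p = 0.52 with an estimated correlation).

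Between the strains (DBA minus B6), the effect of low isoleucine differed for 208 genes, 107 higher and 101 lower, and for 11 with the title-number block. Cd9 fell in B6 females (-0.83 ± 0.20) and rose in DBA males, with a difference of 1.31 ± 0.20 (adjusted p = 6.3e-05, and 0.0093 with the block). Mup21 (1.58 ± 0.35), Osgin1 (1.37 ± 0.30) and Ppargc1a (-1.14 ± 0.31) differed as well, with an adjusted p of 0.24, 0.2 and 0.18 with the block. Markers of lipid-associated and infiltrating macrophages responded less negatively in DBA (4 of 15 past the test, 9 adjusted over the list alone, median 0.95, adjusted p = 1.2e-06, and adjusted p = 0.26 with an estimated correlation). So did Kupffer cell markers (0 of 13, 7 adjusted over the list alone, median 0.66, adjusted p = 1.2e-06, and adjusted p = 0.4 with an estimated correlation), and male-biased genes (1 of 22, adjusted p = 4.9e-06, and adjusted p = 0.4 with an estimated correlation; 10 higher and 1 lower adjusted over the list alone). On average over the sexes interferon genes responded more negatively in DBA (2 of 26, 12 adjusted over the list alone, median -0.47, adjusted p = 8e-09, and adjusted p = 0.4 with an estimated correlation), with medians of -1.30 and -1.24 in B6 and DBA females and -0.34 and -1.10 in B6 and DBA males.

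High isoleucine was compared with control in the same way. In B6 males 674 genes passed, 283 higher and 391 lower (85 and 49 by at least 2-fold); with the title-number block 136 passed, of which 52.2% were higher in place of 42.0%. A fit of the 18 libraries of this class called 195 genes, and a fit of only the 12 libraries compared called 7. Cfd, the complement factor adipsin, rose by 5.20 ± 0.75 on the log2 scale (adjusted p = 1.8e-05, 6 of 6 libraries) and Cidea, a lipid droplet protein, by 3.97 ± 0.57 (5 of 6). Abcg5 rose 1.99-fold and its partner in sterol export, Abcg8, by 0.93 ± 0.16 on the log2 scale, and Srebf1, the regulator of fatty acid synthesis, by 1.17 ± 0.29 (6 of 6 each). Cholesterol synthesis fell: 16 of 25 members were lower and 0 higher (22 lower adjusted over the list alone; median -1.06, adjusted p = 4.5e-17, and adjusted p = 0.13 with an estimated correlation). Hsd17b7 was at -1.45 ± 0.23 and Lss, lanosterol synthase, at -1.06 ± 0.20. Sqle, squalene epoxidase (-4.14 ± 0.81), and Idi1 (-3.07 ± 0.62) fell in 6 of 6 libraries, with an adjusted p of 0.11 and 0.085 with the block. Hsd17b7 lies on chromosome 1 from 169949535 to 169969241, Abcg5 on chromosome 17 from 84658234 to 84683011 and Abcg8 on the same chromosome from 84676302 to 84700333.

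In the same comparison, NRF2 and glutathione genes had 7 of 20 members higher (8 adjusted over the list alone; median 0.33, adjusted p = 0.00016, and adjusted p = 0.28 with an estimated correlation). They included Gstm3 (2.65 ± 0.42) and Gstm1 (1.10 ± 0.18), glutathione transferases with similar copies, and Gsta4 (0.96 ± 0.19). CAR and PXR targets had 5 of 16 higher (7 adjusted over the list alone; median 0.43, adjusted p = 0.00082, and adjusted p = 0.39 with an estimated correlation). Lipid droplet genes had 5 of 24 higher and 2 lower (6 and 2 adjusted over the list alone; median 0.31, adjusted p = 0.0066, and adjusted p = 0.27 with an estimated correlation). PPARA targets had 4 of 35 lower (7 adjusted over the list alone; median -0.08, adjusted p = 0.00034, and adjusted p = 0.42 with an estimated correlation). Cyp4a14 was at -1.22 ± 0.18 and Ehhadh at -0.97 ± 0.22. Gluconeogenesis had 1 of 18 lower (7 lower and 1 higher adjusted over the list alone; median -0.33, adjusted p = 0.00073, and adjusted p = 0.13 with an estimated correlation). The unfolded protein response (1 of 23 lower, 4 adjusted over the list alone, median -0.32), male-biased genes (0 of 22, median -0.30) and periportal genes (1 of 12 lower, 2 adjusted over the list alone, median -0.22) had an adjusted p of 0.00068, 0.0019 and 0.038, and 0.57, 0.55 and 0.58 as the adjusted p with an estimated correlation. Immune cell markers were higher as lists: infiltrating macrophages (2 of 15 past the test, 6 higher and 2 lower adjusted over the list alone, median 0.56, adjusted p = 0.004), MHC class II (0 of 7, 7 adjusted over the list alone, median 0.69, adjusted p = 0.0034), lymphocytes (0 of 19, median 0.64, adjusted p = 0.0046) and neutrophils (0 of 4, 2 adjusted over the list alone, median 0.87, adjusted p = 0.049, or 0.053 without B6 female control library 4 or without DBA male high isoleucine library 3). Their values were 0.47, 0.51, 0.47 and 0.27 as the adjusted p with an estimated correlation, and 0.68 for stellate cell genes (0 of 22, median 0.25, adjusted p = 0.039). Cxcl1 rose by 2.02 ± 0.33 and Ccr2 by 0.85 ± 0.26. Of the 3 measured adipose markers 1, Cfd, passed the test (2 adjusted over the list alone; median 0.47, mean 2.02, adjusted p = 0.00023, and adjusted p = 0.0022 with an estimated correlation). Gdf15, a stress-induced hormone, rose by 1.97 ± 0.55 (6 of 6 libraries, adjusted p = 0.026, and 0.11 with the block).

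In the other classes few genes passed with high isoleucine. In B6 females edgeR called 0 genes (846 at an unadjusted p under 0.05, 2 with DESeq2, 0 with voom). DBA females had 1 (357 unadjusted, 3 with DESeq2, 0 with voom or the block), and DBA males 2 (1261 unadjusted, 14 with DESeq2, 2 with voom, 0 with the block). The gene in DBA females was Suv39h2, a histone methyltransferase (3.25 ± 0.57, 5 of 6 libraries, adjusted p = 0.0039, and 1 with the block). In DBA males they were Fbxo32, a ubiquitin ligase (0.92 ± 0.18, 6 of 6, adjusted p = 0.018, and 0.29 with the block), and Cpne5, a copine chosen after its values were seen (4.03 ± 0.75, 6 of 6, adjusted p = 0.014, and 0.85 with the block). Averaged over the classes edgeR called 0 genes (685 unadjusted, 5 with DESeq2, 0 with voom or the block). With fry 0 of the 12, 15 and 13 lists that camera called with high isoleucine in B6 females, DBA females and DBA males kept their call, and 0 of 14 on average. By camera, cholesterol synthesis had medians of 0.38 in DBA females and 0.26 in DBA males (adjusted p = 5.7e-10 and 0.00016, and 0.22 and 0.65 as the adjusted p with an estimated correlation). Endothelial markers had medians of -0.23 and -0.38 (adjusted p = 3.1e-09 and 4.1e-08, and 0.18 and 0.35 as the adjusted p with an estimated correlation). Mitochondrially encoded genes had a median of -0.48 in DBA males (0 of 13 past the test, 9 adjusted over the list alone, adjusted p = 1.2e-07, and adjusted p = 0.35 with an estimated correlation). In B6 females infiltrating macrophage markers had a median of -0.55 (adjusted p = 0.00039, or 0.091 without B6 female control library 4, and adjusted p = 0.51 with an estimated correlation). On average, gluconeogenesis had a median of -0.14 (0 of 18, 2 lower adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.043 with an estimated correlation), a call that fry did not keep.

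**Figure D4:**
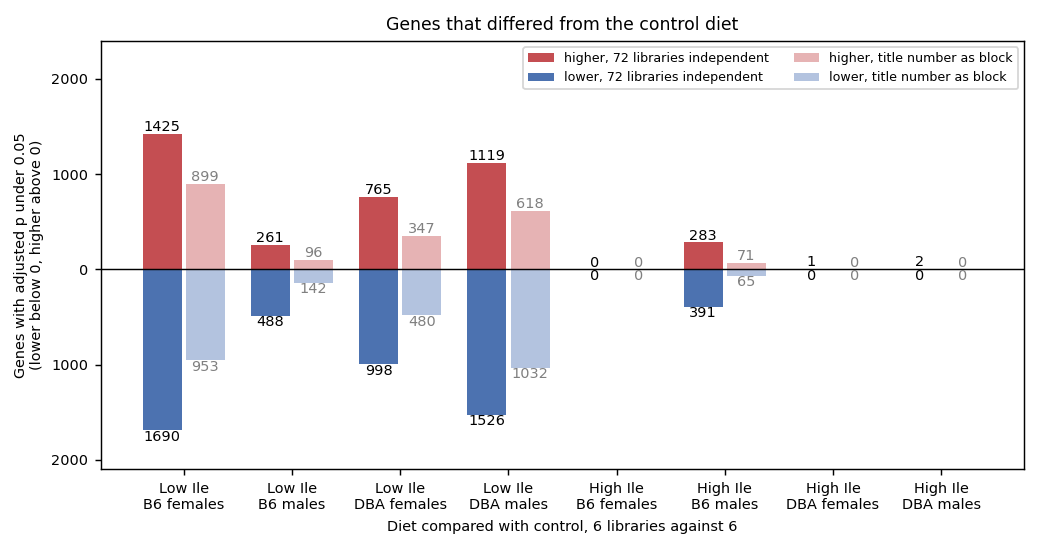
Number of genes past the test (bars, up for higher and down for lower) for each diet against control by strain-sex class, with 6 libraries per group; pale bars are fits with the title-number block. Low isoleucine gave 3115, 749, 1763 and 2645 genes and high isoleucine 0, 674, 1 and 2 in B6 females, B6 males, DBA females and DBA males.

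High against low isoleucine, averaged over the classes, gave 6520 genes, 3419 higher and 3101 lower with high isoleucine. Interferon genes were higher in 25 of 26 cases (median 1.02, adjusted p = 5.3e-25, and adjusted p = 0.049 with an estimated correlation). Kupffer cell markers were higher in 12 of 13 with 1 lower (median 0.57, adjusted p = 0.01, and adjusted p = 0.62 with an estimated correlation). Of 18 gluconeogenesis genes 12 were lower and 1 higher (median -0.34, adjusted p = 0.00058, and adjusted p = 0.12 with an estimated correlation). Fgf21, a liver hormone of the fasting and amino acid responses, was lower by a log2 difference of -0.68 ± 0.20 (adjusted p = 0.005). The effect of high isoleucine differed between strains (DBA minus B6) for 69 genes (38 higher and 31 lower, 55.1% higher; 193 with DESeq2, 44.0% higher; 32 with voom, 40.6% higher; 0 with the block). Cholesterol synthesis held 12 of them (18 of 25 adjusted over the list alone; median 0.89, adjusted p = 3.2e-21, and adjusted p = 0.088 with an estimated correlation). Sqle was at 4.65 ± 0.79 and Hsd17b7 at 1.15 ± 0.22 (adjusted p = 0.33 and 0.17 with the block). Gstm1 (-0.83 ± 0.18) and Abcg5 (-0.73 ± 0.17) responded more in B6, each with an adjusted p of 0.17 with the block. These terms average the sexes, and in B6 females 0 genes passed with high isoleucine, against 674 in B6 males. Among B6 female controls Sqle was 6.82 CPM in library 4 and at most 1.42 CPM in the others. Between the sexes edgeR called 0 genes (1001 unadjusted, 5 with DESeq2, 0 with voom or the block).

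Panel genes are given as CPM (mean ± SD, 6 libraries per group). Fgf21 ranged from 15.2 ± 9.76 in B6 males on high isoleucine to 63.1 ± 43.9 in DBA males on low isoleucine, and Pck1, the gluconeogenic enzyme, from 1270 ± 302 in DBA females on high isoleucine to 3070 ± 467 in B6 males on low isoleucine. Neither passed any comparison of a diet with control, nor did Igf1, insulin-like growth factor 1 (337 ± 39.3 to 793 ± 56.9), Fasn, fatty acid synthase (39.5 ± 7.08 to 94.1 ± 22.9), Cidec, a lipid droplet protein, or Trib3, a pseudokinase induced by ATF4 (6.24 ± 1.79 to 21.2 ± 7.86). Cidec was 38.1 ± 28.1 in B6 male and 1.62 ± 0.877 in DBA female controls. Cyp7a1 went from 103 ± 107 to 252 ± 42.2 in B6 females with low isoleucine (adjusted p = 0.019, higher in 6 of 6 libraries) and from 310 ± 100 to 131 ± 113 in DBA males (adjusted p = 0.026, lower in 5 of 6). Scd1 went from 9020 ± 6040 to 2220 ± 912 in DBA males (adjusted p = 0.0028, 6 of 6). Srebf1 fell from 122 ± 25.9 to 56 ± 11.5 in DBA males with low isoleucine (adjusted p = 0.0036) and rose from 47.8 ± 29.7 to 108 ± 38.9 in B6 males with high isoleucine (adjusted p = 0.014), in 6 of 6 libraries each. Gdf15 went from 4.99 ± 2.39 to 1.53 ± 2.47 in B6 females with low isoleucine (adjusted p = 0.011, 5 of 6). Asns was low outside B6 males: it went from 0.474 ± 0.330 to 1.99 ± 1.70 in DBA males with low isoleucine (adjusted p = 0.043, 6 of 6, and 0.28 with the block), and was 6.35 ± 6.87 in B6 male controls. Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, lay between 62.3 ± 4.89 and 114 ± 10.4 and rose with low isoleucine on average by 0.18 ± 0.05 on the log2 scale (adjusted p = 0.0055).

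**Figure D5:**
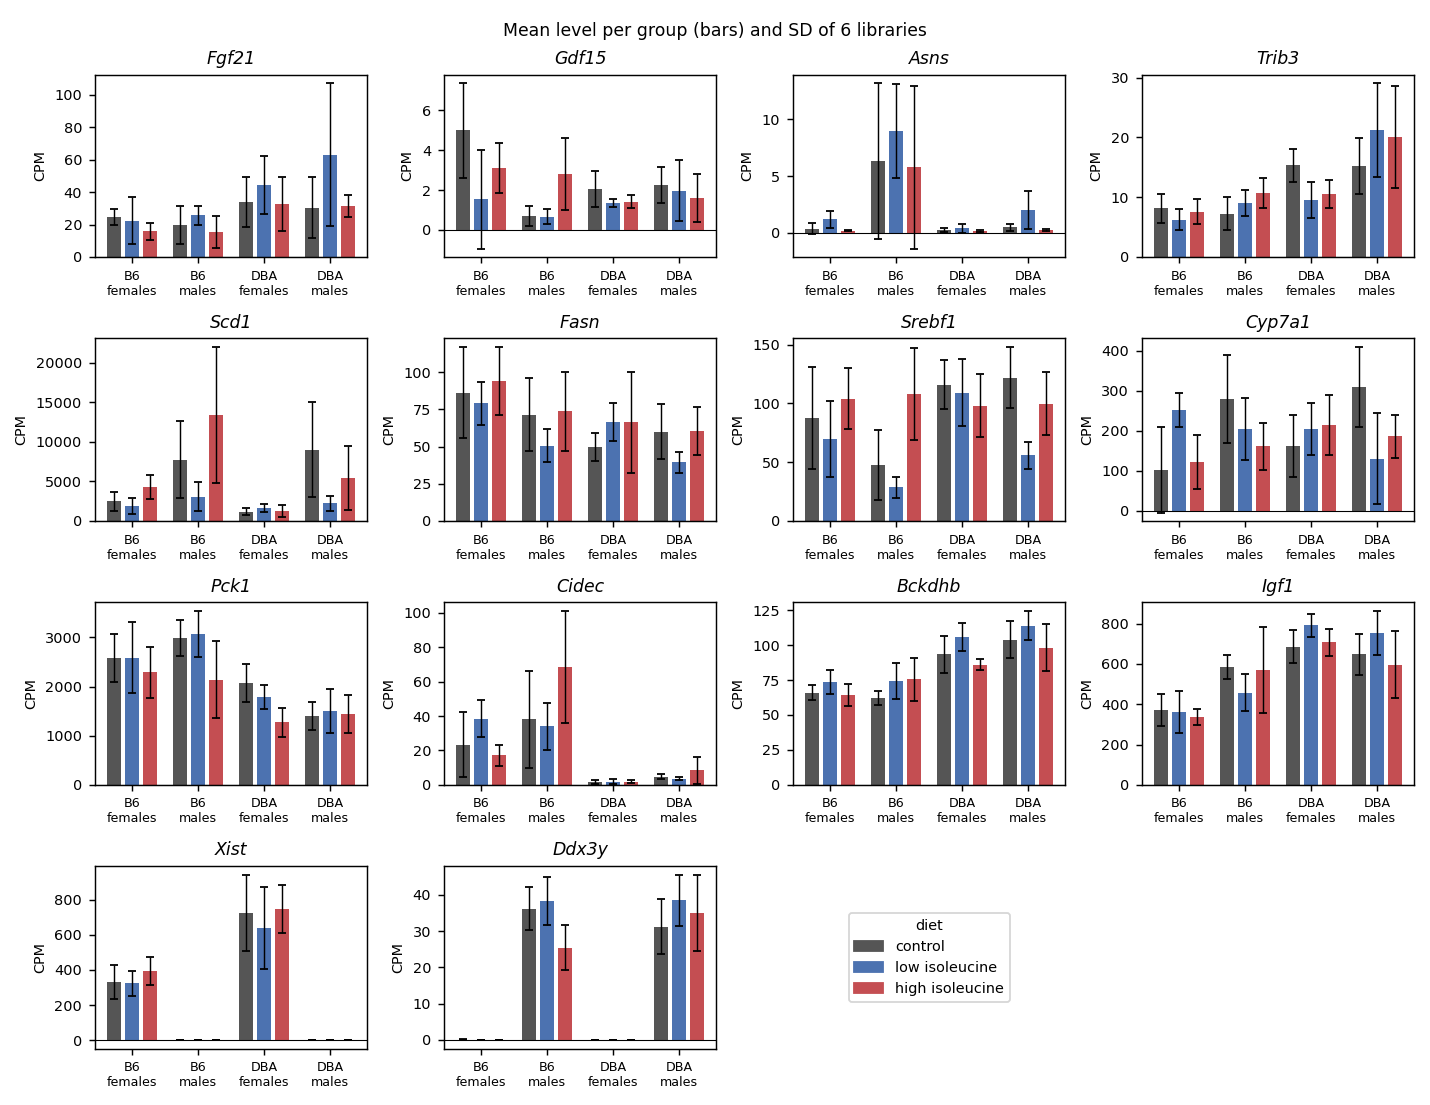
Level in CPM (bars, group mean; error bars, SD of 6 libraries) of the 12 panel genes, Xist and Ddx3y by strain-sex class and diet. Cyp7a1 was 252 ± 42.2 in B6 females and 131 ± 113 in DBA males on low isoleucine.

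Of 5682 genes called with low isoleucine in at least 1 class, 3724 were called in 1, 1410 in 2, 464 in 3 and 84 in 4, of which 22 were higher and 62 lower in all 4. The calls overlapped more than independent lists would: B6 and DBA females shared 434 higher and 557 lower genes against 72.9 and 112.8 for independent lists, and B6 and DBA males 141 and 210 against 19.5 and 49.8. B6 females and DBA males shared 249 and 506 against 106.6 and 172.5, and 76 genes were called in opposite directions. Correlations of fold changes between classes were 0.25 to 0.47 across genes, which are not independent replicates. Low and high isoleucine shared their controls within a class. Across genes, which are not independent replicates, the correlation of their fold changes was 0.24, 0.01, 0.10 and 0.39 in B6 females, B6 males, DBA females and DBA males, against means of 0.54, 0.47, 0.52 and 0.41 in 100 simulations without diet effects, drawn from the spread of title-number means. The highest simulated correlations were 0.96, 0.95, 0.96 and 1. The simulations therefore spread widely, and their means do not show whether an observed correlation lies below chance. With the controls split between the comparisons the observed correlation was -0.05, -0.20, -0.21 and 0.08. The covariances were 0.0261, 0.00171, 0.00821 and 0.0489, and the means of the simulated covariances 0.04, 0.0393, 0.0382 and 0.0312. Without a spread of the simulated covariances no conclusion is drawn from them. In B6 males 23 genes were called in the same direction with both diets, against 17.7 for independent lists, and 41 in opposite directions.

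On the control diet, males and females differed in 3919 genes, 1990 higher and 1929 lower in males. All 22 male-biased genes were higher (median 4.11, adjusted p = 6.2e-61, and adjusted p = 1.6e-06 with an estimated correlation). Of 26 female-biased genes 24 were lower and 1 higher (median -7.89, adjusted p = 1.6e-05 with an estimated correlation). The Y-linked Eif2s3y (10.93 ± 0.24), Ddx3y (10.49 ± 0.38), Kdm5d (10.01 ± 0.26) and Uty (9.57 ± 0.30) led the rises with Cyp4a12b (9.05 ± 0.45). Xist (-12.22 ± 0.31), Sult2a1 (-13.41 ± 0.98), Sult2a2 (-12.28 ± 0.70), Cyp3a41a (-12.62 ± 0.78) and Cyp3a41b (-13.49 ± 1.35) led the falls. Levels near 0 in the lower sex make these fitted folds uncertain in size. Cholesterol synthesis was higher in males (19 of 25, 21 adjusted over the list alone, median 0.74, adjusted p = 4.3e-10, and adjusted p = 0.26 with an estimated correlation). Lymphocyte markers were lower (16 of 19 with 1 higher, 17 and 1 adjusted over the list alone, median -1.13, adjusted p = 4e-06, and adjusted p = 0.14 with an estimated correlation). DBA and B6 differed in 6787 genes, 3428 higher and 3359 lower in DBA, folds that include the mapping of DBA reads to the C57BL/6J reference. Interferon genes were higher in DBA (22 of 26 with 1 lower, median 0.84, adjusted p = 1.3e-08, and adjusted p = 0.37 with an estimated correlation). Stellate cell genes (18 of 22 lower, median -0.72, adjusted p = 3.9e-05), infiltrating macrophage markers (11 of 15, 12 adjusted over the list alone, median -1.31, adjusted p = 0.00021) and PPARA targets (20 of 35 lower, 1 higher, median -0.28, adjusted p = 1.1e-05) were lower, each with an adjusted p of 0.37 with an estimated correlation. Ifi202b (10.43 ± 0.42), an interferon-inducible gene, C1s2 (9.44 ± 0.21) and Mrap2 (9.18 ± 0.65) were among the genes highest in DBA. Cyp2a22 (-12.01 ± 0.76), Gvin1 (-11.22 ± 0.66) and Trim12a (-9.13 ± 0.28) were among the lowest.

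The authors' deposited table holds 8 comparisons of diets whose diet abbreviations were matched to low and high isoleucine by their values. There, 3078, 774, 1768 and 2634 genes had an adjusted p under 0.05 for low isoleucine in B6 females, B6 males, DBA females and DBA males, and 0, 678, 0 and 2 for high isoleucine. Of the 14609 genes in both, 2862, 650, 1631 and 2464 were called in the authors' deposited table and in the edgeR fit with low isoleucine, and 567 with high isoleucine in B6 males, all with the same direction. Across genes, which are not independent replicates, the correlation of fold changes with the authors' deposited table was 0.84 to 0.96.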

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

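The tests of marker levels, scaling, title numbers, cholesterol synthesis genes and adipose markers below were chosen after the results were seen, and the others were set down before. Interferon response genes were lower with low isoleucine. With Kupffer cell, infiltrating macrophage and lymphocyte marker levels in the model, the diet term of their mean log2 level was -0.97 ± 0.11 (permutation p = 1e-05, the smallest possible). It was -0.98 ± 0.10 without the markers, so lower marker levels do not account for the size of the fall on average. The permutation and the SE values count single libraries as independent. Libraries sharing a title number resemble each other, so the p and the SE values overstate the certainty. Scaling by RLE gave a median of -0.94 and scaling on hepatocyte markers -1.05, and in 4 of 4 classes the difference stayed below -0.2 without the 2 lowest low isoleucine libraries. In B6 males it went from -0.34 to -0.21, and 2 of 6 low isoleucine libraries lay below every control, against 6 of 6 in the other classes. The fall with the markers was smallest in B6 males (-0.35 ± 0.14) and was -0.76 ± 0.23 in B6 females (-1.11 ± 0.19 without the markers), -1.17 ± 0.18 in DBA females and -1.31 ± 0.09 in DBA males. Whether it lies in hepatocytes stays open, because bulk RNA does not separate cell types.

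High isoleucine changed 674 genes in B6 males and at most 2 in another class. With the title-number block 136 genes passed, and a split of the same 12 libraries that kept title numbers together called 132 genes against 7 for the real groups, so variation between title numbers may account for much of the count. Of these genes 45.4% had the same direction with low isoleucine against the same controls. That argues against a deviating control group as the whole cause only if low isoleucine itself left these genes unmoved. Low isoleucine changed 749 genes in this class, and 41 genes were called in opposite directions with both diets, so this cause is not excluded. For cholesterol synthesis a deviating control group stays open as well. There 16 of the 16 genes past the test (100%) also had a negative fold with low isoleucine, 5 of them past the test, although shared controls raise this share without any effect. The list's median was -1.06 with high and -0.62 with low isoleucine, and Sqle ran from 1.33 to 32.3 CPM in these controls against 0.32 to 1.17 with high isoleucine. Adipose tissue in the samples is argued against by a median of 0.42 for the adipose markers other than Cfd, with Adipoq at 0.0336 CPM and Plin1 at 0.0283 CPM. The part of the changes that is due to diet stays open.

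B6 female control library 4 lay toward the low isoleucine livers and held Y-linked counts. All 4 Y-linked genes had counts, Ddx3y 17, Eif2s3y 16, Kdm5d 8 and Uty 3, at 1.57, 1.13, 1.59 and 1.2% of the level in B6 male controls, so RNA of a male liver may be present in it. The other female libraries together held 0 counts of Ddx3y (0.568 CPM here), 6 of Eif2s3y in 4 libraries, 1 of Kdm5d in 1 and 3 of Uty in 2, so Uty alone sets nothing apart. The slope of its deviation on the low isoleucine fold of DBA females was 0.34, below the 0.48 to 0.74 of the low isoleucine libraries, which argues against a liver of that diet under a control label, and the other controls had -0.21 to 0.07. How the library came to this place is open, and it was kept.

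Splits of the same libraries into other groups were counted in fits of only the libraries compared, with the real split among them. They exchange single libraries, although libraries sharing a title number resemble each other, and only 10 splits of a class keep these pairs, so with pairs kept the smallest possible share is 1 in 10 and chance cannot be excluded at the level of 5 in 100. For low isoleucine 1 of 100 splits was as large as the real one in B6 females (2325 genes, highest other 1571), B6 males (632, highest other 547), DBA females (1846, highest other 21) and DBA males (2118, highest other 505), which excludes a chance division of single libraries but not of pairs. The 1571 and the 547 came from splits that kept title numbers together, which points to a structure of the samples, and with the block 1852 and 238 genes passed. Of such splits the highest other count was 2 in DBA females and 1 in DBA males. For the averages, the sexes, the strains and the differences of effects no splits that keep pairs were made. On average 1 of 80 splits was as large (5828, highest other 1145). With 0 real calls every split is as large by construction, so the splits test nothing for high isoleucine in B6 females (100 of 100, highest other 1, and 1571 in a title-number split), DBA females (100 of 100, highest other 2, and 85 in a title-number split), DBA males (100 of 100, highest other 65) and on average (80 of 80, highest other 24). In B6 males 1 of 100 was as large (7, highest other 1, apart from the title-number split with 132). High against low isoleucine had 1 of 80 (6447, highest other 5), sex 1 of 100 (3634, highest other 7) and strain 1 of 100 (6542, highest other 1). For the difference of the low isoleucine effect between strains 3 of 80 were as large (259, highest other 1509) and for that of the high isoleucine effect 2 of 80 (23, highest other 343). Exchanging libraries between diets within a class also breaks up any average diet effect, part of which then enters the difference. These splits therefore cannot test a difference of effects, and no conclusion is drawn from their counts. The same limit holds between the sexes, where 1 of 80 was as large for low isoleucine (1093, highest other 131). For high isoleucine between the sexes, with 0 real calls, it was 80 of 80 by construction (highest other 339).

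Of 156 groups of values tested for an outlying library 23 were marked, and chance marks about 1 in 20 where values are normally distributed. The CPM values and totals were tested without a log scale, so a skew toward high values can raise this share. Highest library totals, in units of 1e6 counts, were 48.8 in B6 male controls, 51.1 in B6 males on high isoleucine, 48.5 in DBA females on low isoleucine and 34.8 in DBA males on high isoleucine. Single high CPM values were found for Gdf15 (6.54 in B6 females and 4.97 in DBA males on low isoleucine), Asns (1.37 in B6 female controls, 2.66 in B6 females and 5.36 in DBA males on low isoleucine) and Trib3 (15.6 in DBA females on low and 37.1 in DBA males on high isoleucine). Others were Fasn (72.6 in B6 males on low and 132 in DBA females on high isoleucine), Srebf1 (173 in DBA male controls), Cyp7a1 (314 in B6 female controls) and Igf1 (842 in DBA females and 916 in DBA males on high isoleucine). Cidec had 61.2 in B6 female controls, 58.4 in B6 females on low isoleucine, 3.38 in DBA female controls, 4.58 in DBA females on low isoleucine and 24.1 in DBA males on high isoleucine. Bckdhb had a single low value of 66 in DBA males on high isoleucine.

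The low isoleucine effect differed between strains (DBA minus B6) for 208 genes, and for 11 with the block. Of 125 genes named in the text 8 passed, and 1 with the block: Cd9 1.31, and without it Ifi44 -1.10, Ppargc1a -1.14, Pparg -0.73, Mup21 1.58, Lpin1 -1.68, Osgin1 1.37 and Saa1 2.90. Between the sexes (male minus female) 999 genes differed, and 300 with the block. Of the named genes 29 passed, and 11 with the block: Cyp7a1 -1.66, Cry1 -1.13, Ciart -3.22, Cyp4a14 0.76, Gpt2 -0.83, Thrsp -3.10, Bdh1 0.77, Vnn1 0.91, Vldlr 2.20, Cd4 -1.55 and Cpne5 2.50. Those not past the test with the block were Trib3 0.93, Scd1 -1.74, Gbp10 1.86, Usp2 -2.34, Ehhadh 0.70, Gadd45b 1.29, Pparg -0.64, Otc -0.40, Ahcy -0.48, Tat -1.03, Bhmt -0.93, Ccne1 -1.61, Mup21 -1.59, A1bg 4.50, Mt2 -2.01, Cd9 0.71, Cfd -4.42 and Hsd17b7 -0.67.

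The high isoleucine effect differed between strains for 69 genes, and for 0 with the block. Of the named genes 17 passed, and 0 with the block: Sult1e1 -2.75, Cyp4a14 0.71, Stard4 1.11, Cyp2b9 -3.57, Saa1 2.97, Cfd -5.96, Gstm3 -1.61, Gstm1 -0.83, Gsta4 -0.86, Sqle 4.65, Idi1 3.4, Lss 0.86, Hsd17b7 1.15, Abcg5 -0.73, Abcg8 -0.68, Fbxo32 0.73 and Cpne5 3.89.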

How the results depend on the processing

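Fits without B6 female control library 4 or without DBA male high isoleucine library 3 were chosen after the results were seen. No named gene and no called list changed direction under another setting. However, of 557 results for genes picked by the naming rule, 163 lost the threshold with the title-number block. With libraries of a number summed 165 of them lost it, and without a filter 65. In the fit of 18 libraries 90 of 395 lost it. The share of higher genes among the calls crossed 50% in several comparisons. Among these it went from 45.3% to 57.1% without a filter for low isoleucine between sexes, from 42.0% to 52.2% with the block for high isoleucine in B6 males, and from 55.1% to 44.0% with DESeq2 and 40.6% with voom for high isoleucine between strains. Counts that moved more than 1.5-fold follow, and the cause was not tested. Low isoleucine in B6 females gave 1852 genes with the title-number block and 1672 with libraries of a number summed. In B6 males it gave 465 without a filter, 1715 with quality weights, 238 with the block, 223 with sums and 335 in the fit of 18 libraries. In DBA females it gave 2811 with quality weights, 827 with the block and 713 with sums, and in DBA males 1650 with the block and 1313 with sums. High isoleucine in B6 females gave 2 with DESeq2. In B6 males it gave 307 without a filter, 386 with quality weights, 136 with the block, 51 with sums and 195 in the fit of 18 libraries. In DBA females it gave 3 with DESeq2 and 0 with voom, quality weights, the block, sums and the fit of 18 libraries. In DBA males it gave 14 with DESeq2, 1 with quality weights and 0 with the block, sums and the fit of 18 libraries, and on average 5 with DESeq2. For low isoleucine, the difference between strains gave 109 without a filter, 347 with DESeq2, 368 with quality weights, 11 with the block and 25 with sums. The difference between sexes gave 611 without a filter, 2262 with quality weights, 300 with the block and 164 with sums. For high isoleucine, the difference between strains gave 34 without a filter, 193 with DESeq2, 32 with voom and 0 with the block or sums, and that between sexes 5 with DESeq2 and 1 with quality weights. Males against females gave 2558 with sums. Camera called 205 of 578 list results; 8 kept their call with an estimated correlation and 197 lost it, and fry kept 86, ended 119 and added 31. Leaving out either library moved no count more than 1.5-fold.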

Other observations

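The genes of this paragraph were chosen after the values were seen, from the 84 genes that passed the test with low isoleucine in all 4 classes. Car3, a carbonic anhydrase of hepatocytes and fat cells, fell by 1.75 ± 0.23 on the log2 scale on average (adjusted p = 7.8e-09), with -1.70 in B6 females, -2.11 in B6 males, -1.38 in DBA females and -1.81 in DBA males. Blnk, a B cell linker protein, fell by 1.48 ± 0.16, Wfdc2, a secreted epithelial protein, by 1.64 ± 0.15 and Gpc1, a heparan sulfate proteoglycan, by 1.5 ± 0.14. Clpx, a subunit of a mitochondrial protease, rose by 1.01 ± 0.10, Slc45a3, a sugar transporter, by 1.16 ± 0.11 and Cdo1, which breaks down cysteine, by 0.46 ± 0.05. Each lay on the side of its fold in 6 of 6 low isoleucine libraries of every class. With the title-number block the adjusted p of Car3 was 0.062 in B6 males and 0.12 in DBA females, that of Wfdc2 0.13 and that of Gpc1 0.29 in DBA females.

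Dbp fell with low isoleucine in all 4 classes. Interferon genes fell in B6 females, DBA females and DBA males. In B6 males 2 of 26 passed the test, Ifit1 among them (-1.07), and the mean log2 level of the list differed from control by -0.34. The genes past the test with high isoleucine were mostly those of B6 males (674, and 136 with the title-number block). With an estimated correlation the adjusted p of the interferon list was 0.16 in B6 females, 0.68 in B6 males, 0.02 in DBA females and 0.057 in DBA males. The effect of high isoleucine differed between strains for 69 genes and for 0 with that block, and between sexes for 0. The clock genes cannot be tied to diet alone, since the labels give no time of day and groups killed at different times would differ in Dbp and Arntl. Other genes whose level varies over the day could differ for the same reason. Which of the called genes these are was not tested. Measurements that were not made here are the time of sampling, the cell type in which Ifit1 and its relatives fell, and what the title number stands for.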
